A study of Macaca mulatta with 107 samples.

How the data were processed

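The series holds 107 array samples of sorted CD3 T cells from rhesus macaques, in 6 groups taken from the group label of each sample. Per the labels' protocols, total RNA was extracted from lysed cells and biotinylated cRNA was made with the Affymetrix 3' IVT Plus protocol. The values deposited by the authors are log2 expression values of 26383 probe sets, and RMA is the only tool in the submitters' processing notes, with no version. They run from 1.22 to 16.4, and array medians from 6.16 to 6.68. No other scale, filter or adjustment is given in the sources used here, so the data were examined for them. The standard deviation of probe sets over all samples has a sharp lower edge at 0.214, with 2307 probe sets within 5% above it, so a filter on variability before deposit is likely. Among healthy controls the batch label accounted for a median of 2.37% of a probe set's variance, where 100 shuffles of that label gave 10.2% to 14.4%. Given group, it accounted for 0.83% over all samples, against 6.99% to 9.77% in shuffles. Both lie below every shuffle, as values would after an adjustment for batch with the groups in its model, a step that the labels do not name and that is inferred here. The batch term was kept in the fit, since fits of adjusted values without it count too many degrees of freedom. The deposited values hold no control probe sets with AFFX names, so the planned check of RNA quality could not be run. The highest correlation between 2 samples was 0.992, and no sample was treated as a copy of another.

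The platform annotation named 1 gene for 14060 probe sets and several for 178, and 12145 had no entry and are unnamed here. Symbols were updated through the gene ID for 13900 probe sets in the RefSeq table, and 160 kept the older symbol. Each of 8540 genes was represented by its probe set with the highest mean over all samples, and 3368 genes had more than 1. Of the fixed panel ITGA4, ITGB7, CCR9, HES1, DTX1, GZMB, MKI67 and IFNG, the genes ITGA4, CCR9 and HES1 are not named in the annotation and not analysed here.

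Each of the 12 comparisons was a contrast in 1 limma fit (version 3.58.1, R 4.3.3; lmFit and eBayes with default settings) over all samples, with group and batch as terms and 92 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Animals are separate within each group, and 3 transplanted animals were also healthy controls. Gene lists (28, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Members were counted over all genes and adjusted over the list alone: in NoRx against healthy controls 23 cell cycle, 9 cytotoxic and 15 interferon genes rose in both counts, and in aDLL4_D15 against NoRx 8 cytotoxic genes fell adjusted over the list alone against 6 over all genes. A list score is the mean over members of a sample's log2 value minus the healthy mean. The lists for ribosomal proteins, pan T cells, B cells, NK cells, plasma cells, erythroid cells, myeloid cells, chemokine receptors, gut homing, Notch receptors, ligands and processing, regulatory T cells, type 2 and type 17 responses and immediate early genes were tested in the same way, and none of them was called in any of the 12 comparisons.

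Genes were named by a rule fixed before the data were examined: in each main comparison the 5 largest increases and 5 largest decreases among called genes with a symbol, the called member of each function list with the smallest adjusted p, and the fixed panel; in the others the 3 largest each way and the list members. The main comparisons were NoRx and aDLL4_D15 against healthy controls, aDLL4_D15 against NoRx, and aDLL4_Nx against aDLL4_D15. Further list members were named after their values were seen. Single genes were run under the alternatives only in the comparisons where the rule named them. The aDLL4 pairs come from the animal label. Over the 8 pairs the correlation of the deviations from the group means was 0.02 to 0.62, 5 of 8 samples correlated best with their own partner, and the median between animals was -0.06. Sample numbers in the labels match in 6 of 8 pairs, so the animal label was used.

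The fit was tested on simulated data with 200 of 8540 genes changed. For NoRx against healthy controls it called 79.1% of genes changed by 0.5 on the log2 scale and 97% of those changed by 1, and for aDLL4_D15 against NoRx 25.4% and 89.6%, with 7 and 9 false calls. For FR104_D15 against NoRx it called 13.4% and 70.1%. No list was called without an effect in any simulated comparison, and a shifted list, with every member moved by 1 on the log2 scale, was found in each of the 12. Genes were simulated without correlation between them, so this could not show false list calls that come from correlated genes. Alternatives covered the animal as a replicate block, the batch term, the samples and batches in the fit, the filter on dim genes, the variance model, array weights, a second quantile normalization, the mean over probe sets, samples taken on the last day of survival and each replicate of the 2 smallest groups. Libraries of high myeloid score, that score as a covariate, and aDLL4_D15 replicate 6 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.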

Results

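Gene expression was measured in CD3 T cells that had been sorted by flow cytometry from the peripheral blood of rhesus macaques (Macaca mulatta), on Affymetrix 3' expression arrays, as 107 samples with 1 array each. The animals were healthy controls or had received a hematopoietic cell transplant (HCT), and the study's title places the work in intestinal graft-versus-host disease (GVHD) and Notch signaling. The protocol speaks of allogeneic and autologous transplants, with prophylaxis after the allogeneic ones. The labels do not say which kind a sample followed, so the kind of transplant in NoRx is open. There were 71 healthy controls from 71 animals. The group labelled NoRx held 12 animals sampled on days 6 to 12 after HCT, each on its last day of survival. The aDLL4_D15 group held 9 samples from days 12 to 15, and the aDLL4_Nx group 8 samples from days 17 to 42, each taken on the last day of survival from animals that were also in the day 15 group. The labels define neither Nx nor what ended survival (death, euthanasia or the end of the study). The last day of survival is here only the day on which the sampling day and the survival label coincide. DLL4 is a ligand of Notch receptors, and the label is read here as treatment with an antibody against it. KY1005_D15 (4 samples, days 14 to 16) and FR104_D15 (3 samples, day 14) were other prophylaxis groups. KY1005 is known as an antibody against OX40 ligand, and FR104 as an antagonist of the costimulatory receptor CD28. Replicates are named by the number in their labels, which starts at 0. Values are log2 differences ± the standard error of the limma fit unless SD is named, and adjusted p-values are limma's with Benjamini-Hochberg adjustment over 8540 genes. The number of arrays limits the precision, and the aDLL4 and NoRx groups shared no batch and were linked only through healthy controls. With batch in the fit, a group's difference from healthy controls rested on the controls of its own batches. These were 31 for NoRx, the same 7 for aDLL4_D15 and aDLL4_Nx, and 6 each for KY1005_D15 and FR104_D15. Healthy means, SDs and list scores are given over all 71.

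The comparison of NoRx with healthy controls asks how circulating T cells differ after a transplant when no prophylaxis is named in the label. Cell cycle genes were higher throughout the list: all 23 measured members rose, and MKI67, a marker of proliferating cells, rose by 2.42 ± 0.19 (adjusted p = 9.64e-20), while MCM2, a part of the replicative helicase, rose by 1.88 ± 0.13. Inhibitory receptor genes also rose, 7 of 11 against 1 that fell. LAG3, which binds MHC class II and restrains T cells, rose by 3.55 ± 0.17 (adjusted p = 7.63e-34), from 7.09 ± 0.42 (SD, n = 71) to 10.63 ± 0.54 (SD, n = 12). ENTPD1 rose by 2.36 ± 0.14 and HAVCR2 by 2.08 ± 0.13, and TOX fell by 0.62 ± 0.12. Of 12 measured cytotoxic effector genes, 9 rose and 1 fell, with granzyme B (GZMB) higher by 1.63 ± 0.20 (adjusted p = 8.48e-12) in 12 of 12 samples. The lineage markers CD8A and CD8B rose by 0.53 ± 0.10 and 0.72 ± 0.14, CRTAM of the same list fell by 0.69 ± 0.21, and CD40LG of the CD4 lineage list fell by 0.77 ± 0.16. The cytokine gene IFNG rose by 1.47 ± 0.32, in 11 of 12 samples, and the chemokine receptor gene CXCR3 by 1.23 ± 0.12.

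Interferon response genes rose in 15 of 20 cases and fell in 1 in the same comparison. IFI27 rose by 3.52 ± 0.27 and ISG15 by 2.11 ± 0.16, both in 12 of 12 samples, while OAS1 fell by 0.35 ± 0.09. Of the glycolysis genes 10 of 15 rose, with LDHA, a subunit of lactate dehydrogenase, higher by 1.13 ± 0.06 (adjusted p = 2.5e-30). Of the oxidative phosphorylation genes 14 of 19 rose and 3 fell, and NDUFB3, a complex I subunit, rose by 0.79 ± 0.07. Naive and resting T cell genes fell in 6 of 8 cases, among them FOXP1, by 0.95 ± 0.09. Among measured Notch genes, DTX1, a Notch-induced gene, rose by 1.93 ± 0.21 (adjusted p = 1.64e-13), while the coactivators MAML2 and MAML3 fell by 1.46 ± 0.12 and 2.17 ± 0.23. The Notch target list had 1 gene higher and 2 lower of 4, and the list of Notch receptors, ligands and processing genes 1 higher and 5 lower of 13. The gut homing integrin subunit gene ITGB7 rose by 0.40 ± 0.10, and GPR15, a receptor of colon-homing T cells, fell by 0.57 ± 0.09.

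The largest increases in NoRx included genes that T cells are not known for. S100A9 rose by 4.63 ± 0.58 and S100A8 by 4.60 ± 0.54, both abundant in neutrophils and monocytes, and the fetal globin gene HBG2 rose by 3.46 ± 0.62. The largest decreases, besides MAML3, were in SOX4 (-3.15 ± 0.43), SMAD7, an inhibitor of TGF-beta signaling (-2.32 ± 0.23), ARMCX4 (-2.09 ± 0.16) and JAKMIP2 (-1.99 ± 0.26). Other members named by rule were BAK1, TNFRSF4, TNFRSF1B and IL17F, which rose by 0.97 ± 0.11, 0.93 ± 0.11, 0.84 ± 0.15 and 0.55 ± 0.08, and CXCR4 and IL4R, which fell by 1.28 ± 0.19 and 0.48 ± 0.16. IL4R, lower in 10 of 12 samples, did not pass with probe sets averaged (-0.05, adjusted p = 0.66), without the libraries of high myeloid score (-0.35, 0.176) or with that score as a covariate (-0.41, 0.0572). These are the libraries whose myeloid score lay above that of every healthy control, 6 in NoRx, 4 in aDLL4_D15, 4 in aDLL4_Nx and 1 in KY1005_D15, and both myeloid settings were chosen after seeing the data. Markers of other cell types moved with these groups: 6 of 13 myeloid, 6 of 8 platelet, 5 of 8 erythroid and 4 of 6 plasma cell genes rose, and 4 of 6 measured pan T cell genes fell. Adjusted over the list alone, 8 inhibitory receptor, 15 oxidative phosphorylation and 7 platelet genes rose, and the counts of the other lists named for this comparison were the same except for 1 plasma cell gene that fell. In all, 4731 of 8540 genes differed, 2623 higher and 2108 lower, and 519 of them by at least 2-fold. The set test called cell cycle, interferon response, glycolysis, inhibitory receptor, oxidative phosphorylation, naive and platelet lists, and none of these calls held with an estimated correlation between genes (adjusted p = 0.093 for cell cycle and for inhibitory receptors, 0.174 for interferon, 0.179 for glycolysis, 0.333 for oxidative phosphorylation and naive, 0.566 for platelet). The cytotoxic list did not pass with the preset correlation either (adjusted p = 0.0613). Over all 12 comparisons the set test made 53 calls with the preset correlation, and 4 with an estimated correlation.

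**Figure D1:**
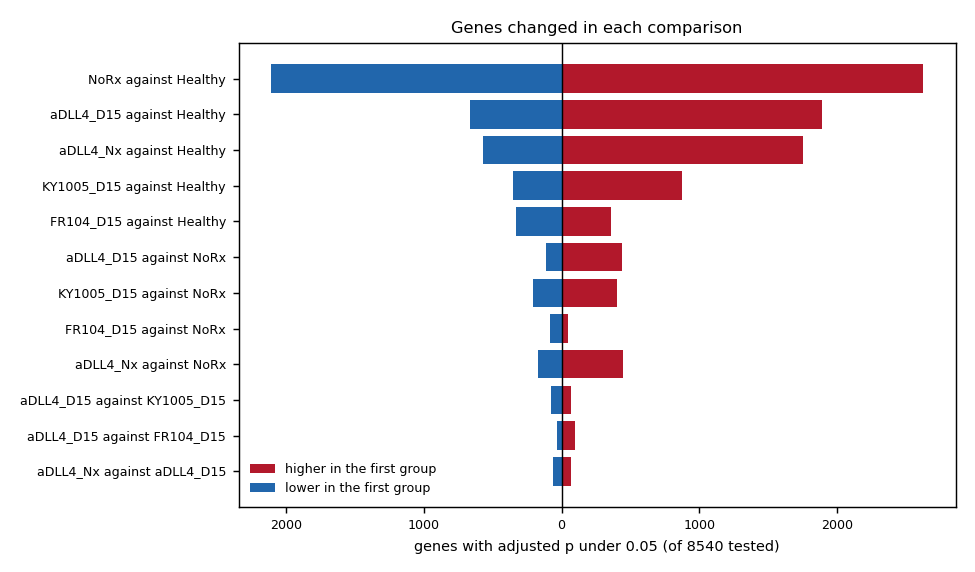
Number of genes with adjusted p under 0.05 (horizontal axis, of 8540 tested) in each of the 12 comparisons, with bars to the right for genes higher and to the left for genes lower in the first-named group. NoRx against healthy controls gave 2623 higher and 2108 lower genes, and aDLL4_D15 against NoRx gave 438 higher and 116 lower.

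The aDLL4_D15 samples were compared with healthy controls to ask which of these differences were present under that treatment. Proliferation and interferon genes were again higher: 22 of 23 cell cycle genes rose, with MKI67 up by 2.05 ± 0.27 and the replication factor GINS2 by 1.72 ± 0.20, and 15 of 20 interferon genes rose, with IFI27 up by 3.44 ± 0.39 and ISG15 by 2.26 ± 0.22, each in 9 of 9 samples. Glycolysis genes rose in 12 of 15 cases (LDHA by 0.73 ± 0.09), oxidative phosphorylation genes in 10 of 19 (NDUFB7 by 0.66 ± 0.09, which did not pass with probe sets averaged, adjusted p = 0.42), inhibitory receptor genes in 7 of 11 (LAG3 by 1.87 ± 0.24) and activation and costimulation genes in 5 of 10. TNFRSF4, which encodes the costimulatory receptor OX40, rose by 1.39 ± 0.16 (adjusted p = 2.01e-11) in 9 of 9 samples. By contrast, GZMB differed by -0.05 ± 0.28 (adjusted p = 0.914), IFNG by 0.37 ± 0.46 (adjusted p = 0.577) and DTX1 by 0.60 ± 0.30 (adjusted p = 0.116, and 0.00886 without a batch term). Of the 12 cytotoxic genes 1 rose, TNFSF10, an apoptosis-inducing ligand, by 1.49 ± 0.29, and 1 fell. The CD8 lineage score lay at -0.42 ± 0.28 (SD, n = 9), below 0 in 8 of 9 samples, against 0 ± 0.26 (SD) in healthy controls, with 1 of 4 genes lower, and the CD4 lineage score at 0.21 ± 0.33 (SD), with neither gene past the test. The integrin genes ITGAE and ITGB7, whose products pair to bind epithelial E-cadherin, rose by 0.82 ± 0.17 and 0.62 ± 0.14, and FOXP3, the regulatory T cell factor, by 0.62 ± 0.15.

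Further genes named by rule in this comparison were ZBED2, S100A8, S100A9 and S100P, which rose by 3.16 ± 0.36, 3.62 ± 0.76, 3.60 ± 0.82 and 2.78 ± 0.55, and CXCR3, CCR1, BAX, IL1RL1 and IL17F, which rose by 1.07 ± 0.17, 0.87 ± 0.23, 0.58 ± 0.11, 0.48 ± 0.12 and 0.42 ± 0.11. Decreases were found for MOXD1 (-1.89 ± 0.34), SLC14A1 (-1.60 ± 0.41), NTN4 (-1.59 ± 0.40), SOX4 (-1.54 ± 0.60), RASGRF2 (-1.46 ± 0.33), FOXP1 (-0.81 ± 0.13) and MAML2 (-0.66 ± 0.17). Of the myeloid markers 7 of 13 rose and 1 fell, and CCR1 did not pass without the libraries of high myeloid score (0.24 ± 0.20, adjusted p = 0.426) or with that score as a covariate (0.32 ± 0.17, 0.166). SOX4 differed by -0.97 ± 0.61 with the score as a covariate (adjusted p = 0.251), by -1.57 ± 0.73 without those libraries (0.101) and by -1.50 ± 0.62 without replicate 6 (0.0576), the sample of the group taken on the last day of survival. None of the 8 platelet genes passed. Adjusted over the list alone, 8 inhibitory receptor, 7 activation, 11 oxidative phosphorylation and 10 myeloid genes rose, and the cell cycle, interferon, glycolysis and naive counts were the same. In all, 2560 genes differed, 1894 higher and 666 lower, 300 by at least 2-fold. The set test called 7 lists, cell cycle, interferon response, glycolysis, oxidative phosphorylation, inhibitory receptor, activation and naive (2 of 8 lower, 1 higher), and with an estimated correlation none passed (adjusted p = 0.084 for cell cycle, interferon, glycolysis and inhibitory receptors, and 0.314 for the other 3).

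**Figure D2:**
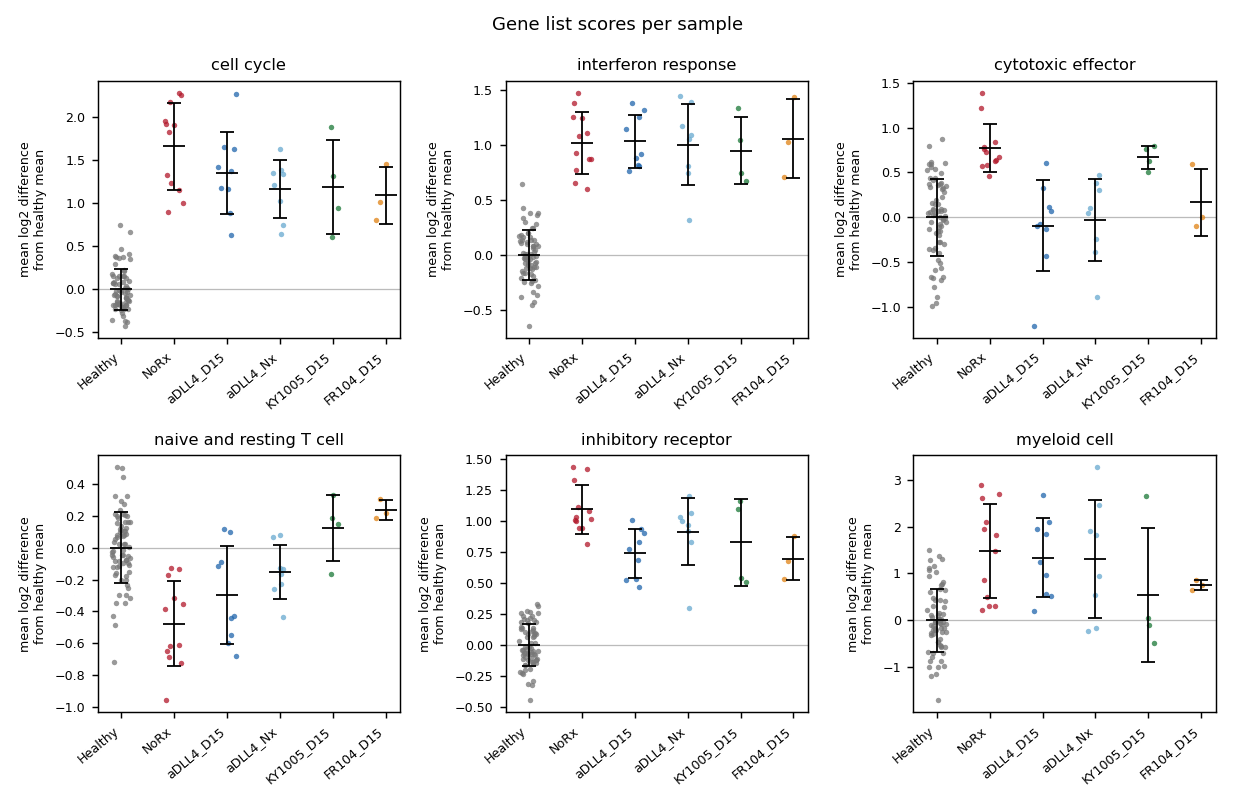
Gene list score of each sample (points; mean over the list's measured genes of the log2 difference from the healthy mean, vertical axis) by group, with the group mean and SD as black bars, for 6 lists. The 4 KY1005_D15 samples had cytotoxic scores from 0.51 to 0.79, and the 9 aDLL4_D15 samples from -1.21 to 0.60.

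The direct comparison of aDLL4_D15 with NoRx tests the difference between those groups itself. Cytotoxic genes were lower in aDLL4_D15: 6 of 12 measured members fell and none rose over all genes tested. GZMB fell by 1.68 ± 0.34 on the log2 scale (adjusted p = 0.000726) in 9 of 9 samples, at 12.83 ± 0.70 (SD, n = 9) against 14.47 ± 0.29 (SD, n = 12), and GNLY, which encodes the pore-forming granulysin, differed by -1.86 ± 0.39. The others were FGFBP2 (-2.25 ± 0.60), GZMH (-1.71 ± 0.52), NKG7 (-1.37 ± 0.39) and CST7 (-1.04 ± 0.34). The CD8 coreceptor genes fell too, CD8A by 0.79 ± 0.17 and CD8B by 0.96 ± 0.23, while CD4 differed by 0.48 ± 0.16 (adjusted p = 0.053). Of the inhibitory receptor genes 3 of 11 fell, HAVCR2 by 1.66 ± 0.23 (adjusted p = 5.1e-07), LAG3 by 1.68 ± 0.29 and ENTPD1 by 1.12 ± 0.25, and TOX rose by 0.68 ± 0.21. DTX1 fell by 1.33 ± 0.36 (adjusted p = 0.0152) in 9 of 9 samples. CCR4, a skin-homing and Th2-associated chemokine receptor gene, rose by 1.75 ± 0.33 (adjusted p = 0.000288).

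In the same comparison none of 23 cell cycle or 20 interferon genes passed alone, and MKI67 differed by -0.37 ± 0.34 (adjusted p = 0.561), IFNG by -1.10 ± 0.56 (adjusted p = 0.247, and 0.0241 without a batch term) and ITGB7 by 0.22 ± 0.18 (adjusted p = 0.509). The largest increases were in SERPINB2 (2.67 ± 0.72), SELENOP (2.23 ± 0.64), PLCL1 (2.02 ± 0.38), the MHC class II gene MAMU-DRA (1.99 ± 0.58) and SMAD7 (1.75 ± 0.40). CCL23 and FCGR3 fell by 2.74 ± 0.49 and 2.22 ± 0.72, and LITAF and HOPX by 1.84 ± 0.57 and 1.04 ± 0.33. Smaller calls were MAML2 (0.80 ± 0.21), NDUFV2 (0.63 ± 0.17), FOXP3 (0.62 ± 0.18) and LDHA (-0.40 ± 0.10). Of the platelet genes 3 of 8 fell, and none of 13 myeloid genes passed. Adjusted over the list alone, 8 cytotoxic genes fell and 1 rose, 3 inhibitory receptor genes fell and 3 rose, and both CD4 lineage genes rose. In all, 554 genes differed, 438 higher and 116 lower, 92 by at least 2-fold, and a second quantile normalization gave 269 higher and 148 lower. The set test called the cytotoxic, CD8 lineage, platelet, cell cycle, type 1 response and inhibitory receptor lists as lower, and with an estimated correlation none passed (adjusted p = 0.203 for cytotoxic, CD8, platelet and inhibitory receptors, 0.301 for type 1 response, 0.573 for cell cycle). With the myeloid score as a covariate 630 genes passed, including all 554 of the fit without it. Without the libraries of high myeloid score 127 passed, and SERPINB2 (adjusted p = 0.294), SELENOP (0.21), LITAF (0.188), SMAD7 (0.186), HOPX (0.183), LDHA (0.12), DTX1 (0.118), MAML2 (0.114), FGFBP2 (0.0968), NDUFV2 (0.0819), FCGR3 (0.0735) and FOXP3 (0.0594) no longer did. Of these, SERPINB2 then differed by 1.34 ± 0.64, SMAD7 by 1.03 ± 0.42 and SELENOP by 1.75 ± 0.73, smaller than before. Differences near or above the earlier ones had larger errors, such as DTX1 (-1.24 ± 0.43), FGFBP2 (-2.16 ± 0.71), LITAF (-1.73 ± 0.70), NDUFV2 (0.64 ± 0.20), FOXP3 (0.74 ± 0.22) and FCGR3 (-2.90 ± 0.89). With probe sets averaged HOPX (-0.31, adjusted p = 0.322), MAML2 (0.70, 0.0936) and FCGR3 (-2.22, 0.0516) did not pass. LDHA did not after a second quantile normalization (-0.23, 0.199), and HOPX (0.0834), FCGR3 (0.0819) and LITAF (0.0549) did not with array weights. Without replicate 6, HOPX (0.0921), FCGR3 (0.0928), LITAF (0.0836) and FOXP3 (0.053) did not pass, with differences that moved by less than 1.5 times. GZMB, GNLY, HAVCR2, CCR4, CCL23, PLCL1 and MAMU-DRA passed under each alternative run for this comparison. The naming rule did not reach GZMH, NKG7, CST7, CD8A, CD8B, LAG3, ENTPD1 and TOX here, so these were not run as single genes under the alternatives.

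**Figure D3:**
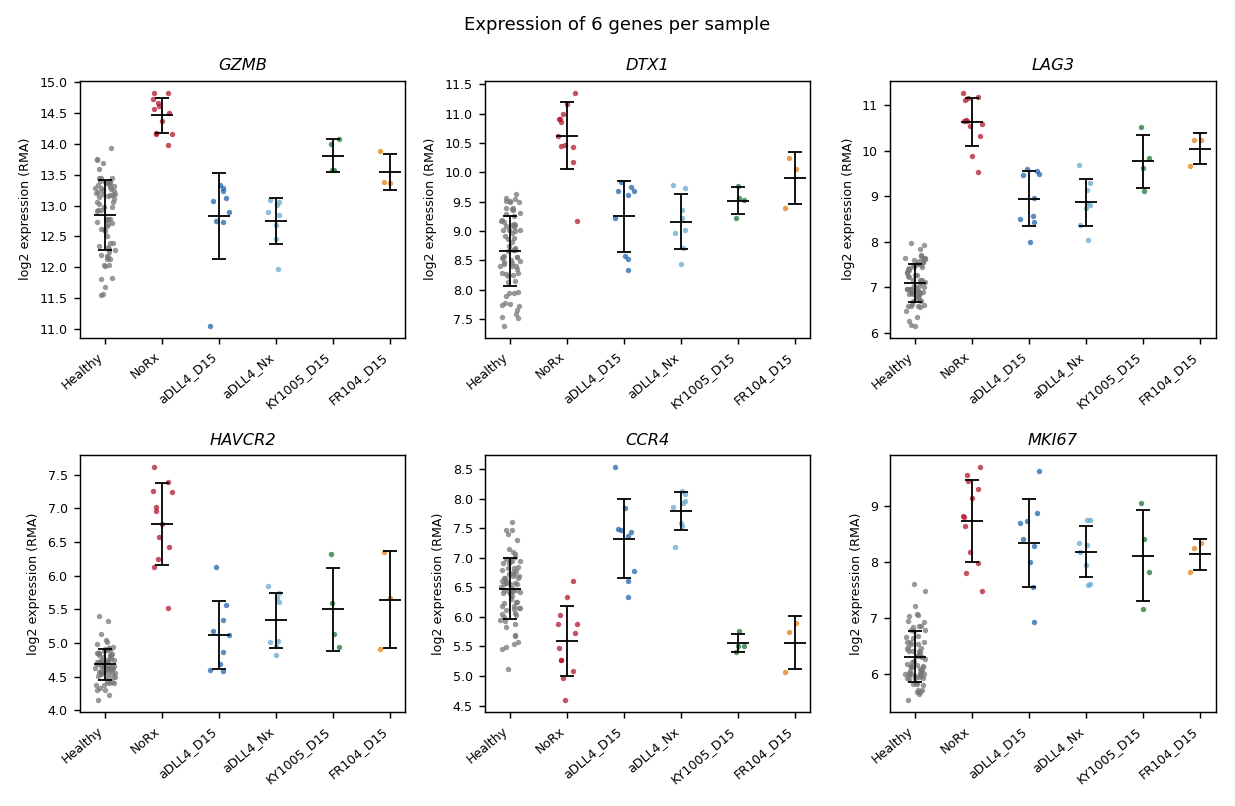
RMA log2 expression (vertical axis) of GZMB, DTX1, LAG3, HAVCR2, CCR4 and MKI67 in each sample (points) by group, with group mean and SD as black bars. GZMB averaged 14.47 in NoRx, 12.83 in aDLL4_D15 and 12.84 in healthy controls.

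The 8 aDLL4_Nx samples were set against all 9 aDLL4_D15 samples, which asks what differed between day 15 and the last day of survival. The reported fit did not pair the 8 animals sampled at both times. It also held replicate 6 of aDLL4_D15, which had no later sample and was itself taken on its last day of survival. A few genes were lower at the later time: SERPINB2 and MMP1, a collagenase, differed by -3.07 ± 0.56 and -3.03 ± 0.57 (adjusted p = 0.000854 for each), the monocyte chemoattractant gene CCL2 by -1.81 ± 0.34, EMP1 by -1.63 ± 0.28 and the IgE receptor gene FCER1A by -1.40 ± 0.27, each in 8 of 8 samples against the day 15 mean. The day 15 values of MMP1 were widely spread, at 5.25 ± 2.21 (SD, n = 9). The error of the fit was pooled over all samples. The mean of MMP1, SERPINB2, CCL2 and EMP1 was highest in aDLL4_D15 replicates 4 (8.52), 5 (7.75), 3 (6.75) and 0 (5.98). Replicates 6, 7 and 8 (3.91, 3.96 and 3.77) lay near the healthy 3.77 ± 0.56 (SD), and replicates 1 and 2 between. All aDLL4_Nx samples lay lower, from 2.89 to 3.63. The count of 8 of 8 therefore does not show a fall of like size in each animal. Increases were found for NABP1 (1.15 ± 0.29), TRIM23 (1.08 ± 0.29), ZNF189 (1.00 ± 0.27), TAGAP (0.96 ± 0.23) and BRI3BP (0.95 ± 0.20), and SLC2A1 and NDUFB7 fell by 0.44 ± 0.12 and 0.34 ± 0.09. GZMB (-0.08 ± 0.27), MKI67 (-0.16 ± 0.26), DTX1 (-0.10 ± 0.29), ITGB7 (-0.21 ± 0.14) and IFNG (0.75 ± 0.44) did not pass, with adjusted p from 0.427 to 0.939. With probe sets averaged neither BRI3BP (0.24, adjusted p = 0.32) nor NDUFB7 (-0.02, 0.952) did. No gene list was called or had more than 1 member past the test. In limma's fit 127 genes differed, 66 higher and 61 lower, a balance that turned to 65 and 99 after a second quantile normalization. The paired values disagreed with each other: with the animal as a random replicate block 550 genes passed, and with the animal as a fixed replicate block over the 8 pairs 0 passed, with 1773 at an unadjusted p under 0.05 and adjusted p from 0.0834 to 0.125 for the called genes named here. With the myeloid score as a covariate 157 genes passed, including all 127 of the fit without it, and without aDLL4_D15 replicate 6 there were 277. Without the libraries of high myeloid score 0 genes passed in limma's fit, with 491 at an unadjusted p under 0.05. SERPINB2 (-1.75 ± 0.58), MMP1 (-1.38 ± 0.67), CCL2 (-0.65 ± 0.37), EMP1 (-0.88 ± 0.32), FCER1A (-0.72 ± 0.29), NABP1 (0.72 ± 0.38) and TAGAP (0.60 ± 0.28) then moved by over 1.5 times. TRIM23 (1.38 ± 0.42), BRI3BP (0.82 ± 0.28), ZNF189 (0.84 ± 0.38), SLC2A1 (-0.35 ± 0.14) and NDUFB7 (-0.29 ± 0.12) moved by less.

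The later aDLL4_Nx samples were also compared with healthy controls and with NoRx. Against healthy controls 21 of 23 cell cycle, 15 of 20 interferon, 8 of 11 inhibitory receptor, 10 of 15 glycolysis, 10 of 19 oxidative phosphorylation and 5 of 10 activation genes rose. ZBED2 rose by 3.69 ± 0.37, TNFSF10 by 1.87 ± 0.30, LAG3 by 1.78 ± 0.25, CHEK1 by 1.71 ± 0.22, TNFRSF4 by 1.31 ± 0.16, CCR4 by 1.31 ± 0.27 and the integrin gene ITGB1 by 1.15 ± 0.28, each in 8 of 8 samples, and SOX4, MMP1 and NTN4 differed by -2.43 ± 0.62, -1.89 ± 0.60 and -1.85 ± 0.41. The rule also named ISG15 (1.76 ± 0.23), CXCR3 (1.20 ± 0.18), BAK1 (0.77 ± 0.16), LDHA (0.69 ± 0.09), NDUFB3 (0.50 ± 0.10), FOXP3 (0.45 ± 0.15), GATA3 (0.38 ± 0.15), FOXP1 (-0.70 ± 0.13) and MAML3 (-1.57 ± 0.33), and HEYL, a Notch target, which differed by -0.42 ± 0.11. Lineage markers moved as well: both CD4 lineage genes rose, CD4 by 0.41 ± 0.14 and CD40LG by 0.70 ± 0.23, with scores from 0.37 to 0.76 in the 8 samples, and CD8A and CD8B fell by 0.35 ± 0.14 and 0.52 ± 0.20. Of the myeloid markers 8 of 13 rose and 1 fell, with S100A8 up by 3.40 ± 0.78 and S100A9 by 3.48 ± 0.85, which did not pass without the libraries of high myeloid score (1.47 ± 0.83 and 1.40 ± 0.89, adjusted p = 0.21 and 0.269). Both genes belong to the list that gives this score, so smaller differences without those libraries were built in. GATA3 did not pass with array weights (0.30, adjusted p = 0.0819), after a second quantile normalization (0.33, 0.0808) or without those libraries (0.45, 0.0626), and FOXP3 did not in the fit limited to batches with both groups (0.45, 0.0534). In counts adjusted over the list alone, 22 cell cycle, 17 interferon, 6 activation and 10 myeloid genes rose. In all, 2322 genes differed, 1752 higher and 570 lower (1334 and 795 after a second quantile normalization). The inhibitory receptor call held with an estimated correlation (adjusted p = 0.0117), and the other 5 did not (adjusted p = 0.0802 for interferon, 0.118 for cell cycle, 0.288 for activation and glycolysis, 0.434 for oxidative phosphorylation).

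Against NoRx, 7 of 12 cytotoxic genes fell and 1 rose in aDLL4_Nx, with GZMB different by -1.76 ± 0.35 (adjusted p = 0.00046) and FGFBP2 by -2.73 ± 0.61, and both CD4 lineage genes rose, CD40LG by 1.47 ± 0.28 and CD4 by 0.58 ± 0.17. CCR4 rose by 2.22 ± 0.33, SELENOP by 2.62 ± 0.65, BIRC3 by 1.41 ± 0.33, ITGB1 by 1.22 ± 0.34 and MAML2 by 1.03 ± 0.21, and DTX1, HAVCR2 and CCL23 fell by 1.42 ± 0.37, 1.45 ± 0.23 and 3.06 ± 0.49. Of the cell cycle genes 4 of 23 fell, MCM2 by 0.90 ± 0.23, and 2 of 8 platelet genes fell. Further genes named by rule were CRISP3 (2.22 ± 0.62), TCF7 (0.77 ± 0.20), NDUFV2 (0.59 ± 0.17), GATA3 (0.56 ± 0.18), LDHA (-0.44 ± 0.11), HOPX (-1.05 ± 0.33) and AFAP1L2 (-2.02 ± 0.52). When adjusted over the list alone, 7 cytotoxic, 7 cell cycle and 4 platelet genes fell. In all, 616 genes differed, 448 higher and 168 lower (273 and 266 after a second quantile normalization), 654 with the myeloid score as a covariate, including all 616 of the fit without it, and 314 without the libraries of high myeloid score. Without those libraries SELENOP, BIRC3, ITGB1, DTX1, FGFBP2, MCM2, HOPX, AFAP1L2, NDUFV2 and GATA3 did not pass (adjusted p from 0.0615 to 0.262). The differences were then smaller for FGFBP2 (-2.01 ± 0.75), AFAP1L2 (-1.47 ± 0.65), SELENOP (2.20 ± 0.77), BIRC3 (1.13 ± 0.40), HOPX (-0.86 ± 0.43), MCM2 (-0.80 ± 0.26) and DTX1 (-1.29 ± 0.45). They were near the earlier ones with larger errors for ITGB1 (1.28 ± 0.44), NDUFV2 (0.60 ± 0.21) and GATA3 (0.55 ± 0.22). With probe sets averaged TCF7 (0.55, adjusted p = 0.0966), NDUFV2 (0.31, 0.146) and HOPX (-0.31, 0.307) did not pass, and GATA3 did not with array weights (0.0505) or after a second quantile normalization (0.056). The CD4 lineage call held with an estimated correlation (adjusted p = 0.0389), and those of the cytotoxic (adjusted p = 0.262), cell cycle (0.352), CD8 lineage (0.15), platelet (0.296) and glycolysis (0.514) lists did not. The CD4 lineage list held only CD4 and CD40LG as measured genes, and CD40LG also belongs to the activation and costimulation list.

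KY1005_D15 and FR104_D15 were each compared with healthy controls. In KY1005_D15, 19 of 23 cell cycle genes and 10 of 20 interferon genes rose, with TPX2, a spindle assembly factor, up by 1.36 ± 0.20 and IFI27 by 3.34 ± 0.50. LAG3 rose by 2.73 ± 0.31 (adjusted p = 2.9e-10), ZBED2 by 3.57 ± 0.46, PLS3 by 3.03 ± 0.52 and LDHA by 0.66 ± 0.11, each in 4 of 4 samples. Of the cytotoxic genes 3 of 12 rose, of the inhibitory receptor genes 5 of 11, of the glycolysis genes 6 of 15 and of the oxidative phosphorylation genes 4 of 19. The CD4 lineage score lay at -0.69 ± 0.28 (SD, n = 4), from -0.99 to -0.39, with 1 of 2 genes lower, and the CD8 lineage score at 0.39 ± 0.17 (SD, n = 4), from 0.17 to 0.52, with 0 of 4 genes past the test. Adjusted over the list alone, 21 cell cycle, 13 interferon, 4 cytotoxic, 6 inhibitory receptor, 9 glycolysis and 7 oxidative phosphorylation genes rose. The B cell gene MS4A1 fell by 2.48 ± 0.57, CD33 by 1.94 ± 0.54 and CD40LG by 1.15 ± 0.29. The rule also named CXCR6 (1.49 ± 0.50), TNFSF10 (1.23 ± 0.37), TNFRSF1B (1.01 ± 0.27), NUMB (0.77 ± 0.17), BAX (0.70 ± 0.14), NDUFB6 (0.51 ± 0.12), TCF7 (-0.62 ± 0.20) and MAMDC2 (-1.87 ± 0.40). None of the 13 measured genes of the myeloid list, which does not hold CD33, or of the 8 of the platelet list passed. In all, 1225 genes differed, 873 higher and 352 lower, and a second quantile normalization turned that balance to 494 higher and 698 lower. The count fell to 288 without replicates 0 and 3, the samples taken on the last day of survival, and CXCR6, TCF7, TNFSF10, TNFRSF1B and CD40LG then did not pass (adjusted p from 0.0585 to 0.458), CXCR6 at 0.90 ± 0.64 and the others with differences that moved by less than 1.5 times. Without replicate 3 it was 687, without replicate 2 it was 810, and CD33 did not pass without replicate 2 (-1.70, adjusted p = 0.0526). With probe sets averaged TNFSF10 (0.37, adjusted p = 0.257), TNFRSF1B (0.30, 0.1), NDUFB6 (0.39, 0.0988) and TCF7 (-0.55, 0.0677) did not pass, and NDUFB6 (0.0888), TNFSF10 (0.0775) and TCF7 (0.0769) did not in the fit limited to batches with both groups. The set test called 6 lists, none of which passed with an estimated correlation (adjusted p = 0.0504 for inhibitory receptors, 0.0722 for cell cycle and glycolysis, 0.0784 for interferon, 0.12 for apoptosis, where 2 of 13 genes rose, and 0.518 for oxidative phosphorylation).

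In FR104_D15, 18 of 23 cell cycle and 11 of 20 interferon genes rose, with TPX2 up by 1.41 ± 0.22 and IFI27 by 4.02 ± 0.54. LAG3 rose by 2.94 ± 0.34, LDHA by 0.86 ± 0.12, BCL2L11 by 1.05 ± 0.23 and the T cell kinase gene TXK by 1.11 ± 0.22, each in 3 of 3 samples. DTX1 rose by 1.28 ± 0.42 (adjusted p = 0.0377), which did not pass with probe sets averaged (0.49, adjusted p = 0.26), without replicate 1 (1.21, 0.15) or without replicate 2 (1.11, 0.248). The immediate early genes FOS and DUSP1 fell by 3.81 ± 1.10 and 2.63 ± 0.65, and SELENOP by 3.67 ± 0.73. S100A8 and S100A9 rose by 4.07 ± 1.07 and 4.81 ± 1.15, and 2 of 13 myeloid genes passed. TNFRSF4 rose by 1.03 ± 0.22, and DLL1 (-1.14 ± 0.33), KLRG1 (-1.49 ± 0.50) and XCL1 (-1.84 ± 0.63) were lower. With p adjusted over the list alone, 21 cell cycle and 15 interferon genes rose, and 2 interferon genes fell. Without replicate 2, FOS (adjusted p = 0.122), DUSP1 (0.0704), S100A8 (0.0728), S100A9 (0.0526), DLL1 (0.261), KLRG1 (0.378) and XCL1 (0.242) did not pass, and without replicate 1 neither FOS (0.0884), TNFRSF4 (0.0682), DLL1 (0.0679), KLRG1 (0.276) nor XCL1 (0.125) did. These differences moved by less than 1.5 times, such as FOS (-3.60 ± 1.27), DUSP1 (-2.37 ± 0.75), S100A8 (3.89 ± 1.24), S100A9 (4.43 ± 1.34) and XCL1 (-1.69 ± 0.73) without replicate 2. With probe sets averaged KLRG1 (-0.62, adjusted p = 0.164) and DUSP1 (-1.67, 0.0655) did not pass. The CD4 and CD8 lineage scores were -0.04 ± 0.46 and 0.28 ± 0.26 (SD, n = 3), with none of their genes past the test. In all, 686 genes differed, 357 higher and 329 lower. That balance depended on single samples and on scaling, with 153 higher and 45 lower (198 in all) without replicate 2, 142 and 213 (355) without replicate 1, and 357 and 383 after a second quantile normalization. The interferon and inhibitory receptor calls held with an estimated correlation (adjusted p = 0.0239 for each), with 5 of 11 inhibitory receptor genes higher, and the cell cycle and glycolysis calls did not (adjusted p = 0.0686 and 0.23).

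Set against NoRx, HAVCR2 fell in both groups, by 1.24 ± 0.28 in KY1005_D15 and by 1.13 ± 0.30 in FR104_D15. Of the naive and resting T cell genes 4 of 8 rose in KY1005_D15, FOXP1 by 0.86 ± 0.18, in a list called with adjusted p = 0.301 with an estimated correlation. In FR104_D15 3 of 8 rose (adjusted p = 0.0848 with an estimated correlation), TXK by 0.98 ± 0.24 and the lymph node homing receptor gene CCR7 by 1.71 ± 0.48, and neither passed without replicate 2 (adjusted p = 0.151 and 0.165). The succinate receptor gene SUCNR1 fell by 1.97 ± 0.27 and 1.87 ± 0.29, and CXCR3 by 0.91 ± 0.25 and 1.24 ± 0.27. CXCR4 rose by 1.76 ± 0.39 and ZBTB20 by 2.23 ± 0.38 in KY1005_D15, and 4 of 8 platelet genes fell, PPBP, a platelet chemokine, with a difference of -4.24 ± 1.27. Further genes named by rule for KY1005_D15 were SIK1 (2.53 ± 0.66), DACT1 (2.16 ± 0.58), NUMB (1.04 ± 0.19), BCL2 (0.76 ± 0.23), LDHA (-0.47 ± 0.12), NDUFB3 (-0.55 ± 0.14), IFI35 (-0.66 ± 0.18), MCM2 (-0.84 ± 0.27), TNFRSF4 (-0.84 ± 0.23) and CCL23 (-2.49 ± 0.58). For FR104_D15 they were PLAAT2 (1.81 ± 0.31), PGAP1 (1.77 ± 0.45), MAML2 (0.99 ± 0.26), NDUFB7 (-0.50 ± 0.14), IFI35 (-0.70 ± 0.20), MCM5 (-0.94 ± 0.27), FES (-1.40 ± 0.36) and BAG2 (-1.46 ± 0.39). Adjusted over the list alone, 4 naive genes rose in each comparison and 6 platelet genes fell for KY1005_D15. None of the 12 cytotoxic genes passed in either comparison. In all, 614 genes differed for KY1005_D15, 405 higher and 209 lower (240 and 644 after a second quantile normalization), 199 without replicates 0 and 3, and 288 without replicate 2. CXCR3, CXCR4, PPBP, BCL2, DACT1, MCM2, SIK1 and TNFRSF4 did not pass without replicates 0 and 3 (adjusted p from 0.0508 to 0.325), with differences that moved by less than 1.5 times. IFI35 did not without replicate 1 (-0.59, 0.0586), and LDHA did not without the libraries of high myeloid score (-0.42, 0.0792). With the myeloid score as a covariate PPBP (-3.43, adjusted p = 0.0596) and MCM2 (-0.83, 0.0512) did not pass. For FR104_D15 133 differed, 49 higher and 84 lower, 9 without replicate 2 and 39 without replicate 0, and with the animal as a random replicate block 221. Of the genes named for FR104_D15, SUCNR1 and PLAAT2 passed under each alternative run, HAVCR2 did not pass without replicate 0 or replicate 1 (adjusted p = 0.258 and 0.0587), and the others did not pass without replicate 2 (adjusted p from 0.0572 to 0.207), each with a difference that moved by less than 1.5 times. With probe sets averaged NDUFB7 had the opposite sign (0.17, adjusted p = 0.589), and MCM5 (-0.39, 0.459), MAML2 (0.87, 0.158) and CCR7 (1.71, 0.0523) did not pass. With an estimated correlation the cell cycle calls, each with 1 gene lower, had adjusted p = 0.803 and 0.548, and the platelet call of KY1005_D15 had adjusted p = 0.301.

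Finally, aDLL4_D15 was set against the other groups sampled near day 15. Against KY1005_D15, CCR4 was higher by 1.75 ± 0.43, CD109 by 1.70 ± 0.33, TNFRSF4 by 1.30 ± 0.25, FOXP3 by 0.94 ± 0.24 and ITGB7 by 0.85 ± 0.24, and CREBRF and FOXP1 were different by -1.60 ± 0.30 and -0.72 ± 0.20, each in 9 of 9 samples. The rule also named SEL1L3 (2.04 ± 0.56), TSR2 (-1.91 ± 0.52) and OSR2 (-2.05 ± 0.55). The cytotoxic, naive and CD8 lineage lists were called lower, with 0, 1 and 0 of their genes past the test over all genes and 0, 5 and 4 adjusted over the list alone, and with adjusted p = 0.372, 0.372 and 0.215 with an estimated correlation. In all, 149 genes differed, 71 higher and 78 lower, a balance that turned to 154 and 58 after a second quantile normalization and to 202 and 133 with array weights. The count was 0 in limma's fit, with 931 at an unadjusted p under 0.05, once the samples taken on the last day of survival (KY1005_D15 replicates 0 and 3 and aDLL4_D15 replicate 6) were left out. FOXP3 then differed by 0.55 ± 0.27, and the other genes named here moved by less than 1.5 times. CREBRF (-0.61 ± 0.22, adjusted p = 0.146) and SEL1L3 (1.32 ± 0.42, 0.0822) did not pass with probe sets averaged. TSR2 did not with array weights (-1.21 ± 0.42, 0.0759), and FOXP1 did not after a second quantile normalization (-0.52 ± 0.20, 0.124). Leaving out 1 KY1005_D15 replicate gave 66 (replicate 0), 62 (replicate 2) or 54 (replicate 3) genes. Against FR104_D15, SELENOP was higher by 4.31 ± 0.90, MAMU-DMA by 2.64 ± 0.72, CCR4 by 1.72 ± 0.46 and CXCR3 by 1.08 ± 0.29, and KIR3DH, STAT3 and TXK were different by -2.42 ± 0.56, -1.78 ± 0.41 and -1.35 ± 0.27. The rule also named ME1 (2.18 ± 0.60), NDUFB7 (0.58 ± 0.16) and JAK-1 (-1.36 ± 0.37), and NDUFB7 had the opposite sign with probe sets averaged (-0.19, adjusted p = 0.596). The median of all genes lay at 0.11 in that comparison, against which each value is to be read. In all, 133 genes differed, 100 higher and 33 lower, 61 without FR104_D15 replicate 0, 243 without replicate 1 and 3 without replicate 2, where none of the genes named here passed. The Notch target, naive and CD8 lineage lists were called lower with 0, 1 and 0 genes past the test over all genes and 0, 3 and 2 adjusted over the list alone (adjusted p = 0.0899, 0.12 and 0.12 with an estimated correlation).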

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

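The tests of CD8 share, of batch, of sampling day between groups and of the myeloid score between the aDLL4 times were chosen after the result was seen, as were leaving out libraries of high myeloid score and that score as a covariate, and the other tests before.

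Genes and list scores within aDLL4_D15, aDLL4_Nx and KY1005_D15 (4 to 9 samples each) were tested for a sample far from the others. Of 188 such sets of values, 12 were past the limit, where chance passes about 1 in 20. That is little above the rate of chance, and the sets are not independent, so each case below may be chance. In aDLL4_D15, replicate 6, the only sample of its group taken on the last day of survival, was lowest in GZMB (11.05 against 12.74 for the next), in the NK cell list score (-1.83) and in the type 1 response score (-0.75), and highest in IL1RL1 (6.84). Replicate 8 was highest in CCL23 (5.04), replicate 1 in GINS2 (9.31), and replicate 7 lowest in the chemokine receptor score (-0.70). In aDLL4_Nx, replicate 0 was highest in MMP1 (2.66) and lowest in the inhibitory receptor score (0.30), and replicate 2 was lowest in NABP1 (6.90). In KY1005_D15, replicate 3 was highest in the myeloid score (2.65, against 0.06 for the next) and in the gut homing score (0.30).

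Probe sets without a gene name, which no comparison of genes used, also changed: 4486 of 12145 for NoRx against healthy controls, 1802 for aDLL4_D15 against healthy controls and 378 for aDLL4_D15 against NoRx. Between the aDLL4 time points the difference from healthy controls itself differed for 127 genes, a count that changed with how animals were paired (550 with the animal as a random replicate block, and 0 in limma's fit with the animal as a fixed replicate block over the 8 pairs, with 1773 at an unadjusted p under 0.05).

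The first pattern weighed is the lower cytotoxic expression in aDLL4_D15 than in NoRx. For sampling day, scores were permuted without a batch term, although aDLL4_D15 shared no batch with KY1005_D15 or FR104_D15. Sampling day stays open: the score of aDLL4_D15 minus that of KY1005_D15 was -0.76 (2-sided exact permutation p = 0.0154, 9 against 4 samples), but minus that of FR104_D15 it was -0.26 (2-sided exact permutation p = 0.441, 9 against 3 samples), both of these groups had treatments of their own, and a decline with day within NoRx could not be judged from 12 samples (Pearson r = 0.12, permutation p = 0.712; Spearman rho = 0.25, p = 0.424; r = 0.48 without the 2 days farthest from the median). A lower share of CD8 T cells stays open: the change of the 6 called genes minus that of CD8A and CD8B was -0.78 ± 0.35, and with the CD8A and CD8B mean as a covariate these genes differed by -0.89 ± 0.40, both past 2 standard errors, but without replicate 6 the values were -0.56 ± 0.34 and -0.70 ± 0.38, within that limit, and over all 12 measured genes the first was -0.04 ± 0.26. A shift shared by all samples of a batch is already taken out by the batch term, within the error of that batch's controls. Against healthy controls of their own batches the 6 genes, chosen by this same comparison, differed by -0.29 ± 0.35 in aDLL4_D15 and 1.36 ± 0.22 in NoRx. The difference of these values, -1.65 ± 0.41, equals the fit over all samples by construction, so that test, and the limit written for it, added nothing. A batch difference limited to the transplanted samples cannot be told apart from the group. An effect of the treatment on cytotoxic cells is the biological candidate and remains a hypothesis.

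The second pattern is the rise of S100A8 and S100A9 in NoRx. Myeloid cells carried through the sort are a candidate source: over the 12 samples their mean rose with that of the other 11 measured myeloid markers (Pearson r = 0.91, permutation p = 0.00014; Spearman rho = 0.86, p = 0.00064; r = 0.91 without the 2 extreme samples). The gate on CD3 would remove such cells, and of their abundant transcripts FCN1 rose by 2.98, LYZ by 2.13 and VCAN by 2.05, but CD14 differed by 0.08 and CSF3R by 0.19. Expression by T cells themselves was not tested.

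The third pattern is the high mean of MMP1, SERPINB2, CCL2 and EMP1 in some aDLL4_D15 samples, from 3.77 to 8.52, against 3.77 ± 0.56 (SD) in healthy controls and 2.89 to 3.63 in the aDLL4_Nx samples. A smaller amount of myeloid cells at the later time is argued against as the cause of the difference between the times, since the myeloid scores differed by only -0.02 ± 0.51 over the 17 samples. With scores so alike a covariate could hardly move the difference of the 4 genes (-2.37 ± 0.54 with the score, -2.38 ± 0.64 without), so that fit adds nothing independent. These fits took the 17 samples as independent, although 8 animals were sampled at both times. Within aDLL4_D15 myeloid cells may still be the source, since the mean rose with the myeloid score over the 9 samples (Pearson r = 0.86, exact permutation p = 0.00415; Spearman rho = 0.72, p = 0.0369; r = 0.75 without the 2 extreme samples). With libraries of high myeloid score left out, 0 genes passed between the times in limma's fit (491 at an unadjusted p under 0.05) and these 4 differed by -0.65 to -1.75, while with the score as a covariate 157 passed, including all 127 of the fit without it. A response at day 15, in myeloid cells or in T cells, was not tested separately and stays open.

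Other splits of the samples into groups of the same sizes, the real split among 100, were run to see how often a random split gave counts as large. For every comparison the share was under 0.05, without adjustment over the comparisons. Except between the aDLL4 times, the splits moved samples across batches, so they do not keep the layout in which each prophylaxis group lay in 1 batch. They therefore leave a difference between batches open. Only the real split reached its count for NoRx against healthy controls (1 of 100, 4731 genes against 1115 in the highest other split), for aDLL4_D15 (2560 against 108), aDLL4_Nx (2322 against 63) and KY1005_D15 (1225 against 525) against healthy controls, and for aDLL4_D15 (554 against 63), KY1005_D15 (614 against 210) and aDLL4_Nx (616 against 483) against NoRx. For FR104_D15 against healthy controls 3 splits did so (686 against 1133) and against NoRx 2 (133 against 188), and for aDLL4_D15 against KY1005_D15 2 (149 against 194) and against FR104_D15 4 (133 against 397). Between aDLL4_Nx and aDLL4_D15 only the real split reached 127 genes (24 in the highest other), but among splits that part all 8 pairs 4 did (127 against 327). Single splits called 397 and 327 genes, above the real counts of 133 and 127, and the reason was not tested.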

How the results depend on the processing

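Leaving out libraries of high myeloid score, that score as a covariate and leaving out aDLL4_D15 replicate 6 were alternatives chosen after seeing the data. The count for NoRx against healthy controls stayed within 1.5 times of 4731 under each alternative run, and those of both aDLL4 groups against healthy controls did so except without a batch term. Of 2807 values of named genes under alternatives, 286 lost their call, 3 gained one and 2 changed sign, and of 4788 values of gene lists 93 lost, 63 gained and 1 changed sign. A change of sign was counted only where the reported or the alternative value passed, and others were counted as the same. The counted changes of sign were NDUFB7 with probe sets averaged, at 0.17 for FR104_D15 against NoRx and -0.19 for aDLL4_D15 against FR104_D15, and the erythroid list between aDLL4_Nx and aDLL4_D15 without libraries of high myeloid score, at -0.56. With an estimated correlation between genes the 53 calls of gene lists came to 4. The fit limited to batches with both groups exists only against healthy controls, so it gives no total of list calls.

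Without a batch term the counts were 4463 for aDLL4_D15, 4168 for aDLL4_Nx, 2418 for KY1005_D15 and 1590 for FR104_D15 against healthy controls, 2297, 2290, 1994 and 937 for aDLL4_D15, aDLL4_Nx, KY1005_D15 and FR104_D15 against NoRx, 1302 and 1278 for aDLL4_D15 against KY1005_D15 and FR104_D15, and 231 between the aDLL4 times. With only the 2 groups compared in the fit, which holds no batch term where they share no batch, they were 1586, 1791, 1521 and 227 against NoRx in the same order, 691 and 323 for aDLL4_D15 against KY1005_D15 and FR104_D15, and 0 between the aDLL4 times by limma, with 1074 at an unadjusted p under 0.05. Only batches with both groups gave 343 for KY1005_D15 and 268 for FR104_D15 against healthy controls.

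Array weights gave 2584 for KY1005_D15 against healthy controls, 1581 and 375 for KY1005_D15 and FR104_D15 against NoRx, and 335 and 214 for aDLL4_D15 against KY1005_D15 and FR104_D15. Probe sets averaged gave 88 for FR104_D15 against NoRx and 200 between the aDLL4 times, a second quantile normalization 87 for aDLL4_D15 against FR104_D15, and leaving out the genes of lowest mean 51 between the aDLL4 times. The animal as a random replicate block gave 221 for FR104_D15 against NoRx and 550 between the aDLL4 times, and as a fixed replicate block over the pairs 0 by limma, with 1773 at an unadjusted p under 0.05. Without day 15 samples taken on the last day of survival, KY1005_D15 gave 288 against healthy controls and 199 against NoRx, aDLL4_D15 against KY1005_D15 gave 0 by limma (931 at an unadjusted p under 0.05) and the aDLL4 times 294.

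Without libraries of high myeloid score the counts were 683 for KY1005_D15 against healthy controls, 127, 314, 284 and 41 for aDLL4_D15, aDLL4_Nx, KY1005_D15 and FR104_D15 against NoRx, 88 for aDLL4_D15 against KY1005_D15 and 0 between the aDLL4 times (491 at an unadjusted p under 0.05 by limma). The score as a covariate gave 80 for FR104_D15 against NoRx and stayed within 1.5 times of the reported count in the other comparisons, with 630 and 654 for aDLL4_D15 and aDLL4_Nx against NoRx and 157 between the aDLL4 times, which held all 554, 616 and 127 reported genes. Leaving out 1 replicate at a time (for FR104_D15 always lowest without replicate 2) gave 687 to 937 for KY1005_D15 and 198 to 718 for FR104_D15 against healthy controls, 288 to 495 and 9 to 99 against NoRx, and, with 1 replicate of the comparison group left out, 54 to 114 and 3 to 243 for aDLL4_D15 against KY1005_D15 and FR104_D15. Without aDLL4_D15 replicate 6, aDLL4_D15 gave 2510 against healthy controls, 514 against NoRx, 140 against KY1005_D15 and 155 against FR104_D15, and the aDLL4 times 277. For each setting the cause was not tested, and fewer samples cannot be the cause where leaving some out raised a count (277 and 294 between the aDLL4 times, 243 and 155 for aDLL4_D15 against FR104_D15, 718 for FR104_D15 against healthy controls). The number of arrays limited small changes most, since for FR104_D15 against NoRx 13.4% of simulated changes of 0.5 on the log2 scale were called.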

Other observations

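The MHC class II genes were looked at after their values were seen, and the tests of survival were written down before.

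MHC class II genes, whose products present antigen, were lower in NoRx than in healthy controls for 3 of 7 measured genes, MAMU-DPA (-1.43 ± 0.23), MAMU-DRA (-1.22 ± 0.34) and MAMU-DQA1 (-0.75 ± 0.19), and none rose. In aDLL4_D15 against NoRx 2 of 7 were higher, MAMU-DRA (1.99 ± 0.58) and MAMU-DMA (1.72 ± 0.51), and none fell. B cells and myeloid cells also express these genes, and MAMU-DMA was not run under the alternatives for that comparison.

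The differences of NoRx and of aDLL4_D15 from healthy controls overlapped: 1500 genes were higher in both, where independent lists would share 582, 546 were lower in both (164), and 20 went opposite ways. With the controls split between the comparisons the counts were 1469 and 481. The correlation of the differences across genes, which are not independent replicates, was 0.76, and 0.75 with split controls. In 100 simulations without any difference between groups, with genes drawn independently, the same fit gave a mean correlation of -0.00288. NoRx and aDLL4_D15 shared no batch, so with batch in the fit their differences already rested on different healthy controls. Neither the split nor the simulations could therefore show an effect of shared controls. The simulations also give no spread for correlated genes.

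The labels do not say what ended survival, and whether list scores at day 15 go with its days was tested over the 9 aDLL4_D15 samples, all of 1 batch, for 6 lists, with 2-sided exact permutation p and adjustment over the lists. None passed. The naive and resting T cell score was nearest (Pearson r = -0.76, exact p = 0.0191, adjusted p = 0.115; Spearman rho = -0.70, exact p = 0.0401; r = -0.73 without the 2 samples farthest from the median). The cytotoxic score gave r = 0.62 (exact p = 0.0718, adjusted p = 0.215; rho = 0.63, exact p = 0.0773; r = 0.94 without 2). For cell cycle r was -0.30 (exact p = 0.439; rho = -0.25, p = 0.512; r = 0.47 without 2), for interferon response -0.25 (exact p = 0.496; rho = -0.06, p = 0.887; r = 0.28 without 2) and for inhibitory receptors -0.34 (exact p = 0.365; rho = -0.11, p = 0.784; r = 0.70 without 2), each with adjusted p = 0.595. Gut homing gave r = 0.0448 (exact and adjusted p = 0.907; rho = 0.28, p = 0.47; r = 0.60 without 2). Several of these changed sign without 2 samples, so they rest on those samples. The samples left out were replicates 4 and 5, with the longest survival (41 and 42 days). Replicate 6 was taken on day 12, its last day of survival, and was kept in each test, so its score does not precede the outcome.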
